A study of Homo sapiens with 6 samples.

How the data were processed

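RNA from HT29 cells carrying a control hairpin (shNC, 3 libraries) or a hairpin against HMGA1 (shHMGA1, 3 libraries) was measured by sequencing. Per the labels' protocols, mRNA was purified with poly-T beads, libraries were made with a Vazyme VAHTS Universal V6 kit for MGI and sequenced on an MGI-SEQ 2000 instrument. Groups and replicate numbers were taken from the sample titles. The genome build was hg38, per the submitters' processing notes. The aligner, the counting tool, its strand setting, its treatment of reads that match several genes and the annotation release are not given in the sources used here.

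A single deposited table was used. Per the file headers it holds FPKM per library (fragments per kilobase of transcript, scaled to the mapped fragments, made by the authors and rounded to 2 decimals) for 31164 genes, of which 30555 have Ensembl IDs and 609 have identifiers of loci outside Ensembl. The same deposited table gives the authors' group levels, a signal on a normalized count scale, together with the authors' log2 fold change, p-value and adjusted p, per the file headers. The tool behind that test is not given in the sources used here. In 2916 genes at 0 in every shHMGA1 library the authors' level for that group was above 0. Differences between groups were therefore tested on FPKM and not on these levels. The levels set the minimum of 200 for genes in the comparison of fold changes. FPKM keeps no depth in its total. Genes at low FPKM (0.3 to 3, from 219 to 249 genes per library) gave an estimate of depth relative to shNC replicate 1. It was 0.76 and 0.84 for shNC replicates 2 and 3 and 0.69, 0.8 and 0.73 for shHMGA1 replicates 1 to 3. The reference, at 1, had 767 such genes. Precision at low FPKM is therefore lowest in shHMGA1 replicate 1. The number of genes listed at 0 ran from 5747 in shNC replicate 1 to 7116 in shHMGA1 replicate 1.

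FPKM was tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (group means, eBayes with a mean-variance trend, two-sided), for 14304 genes with a mean of at least 1 FPKM over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and every adjusted p without another source comes from this test. A fold change on this scale understates the change of genes at low FPKM. Differences are shHMGA1 minus shNC throughout. In counts of list members, rose and fell mean called at an adjusted p under 0.05, so a count can drop while the direction stays. Gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 26 lists with at least 3 tested members. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were run beside it. Single values were compared by exact permutation with scipy 1.17.1 in Python 3.11.15. On simulated data for shHMGA1 against shNC (14128 genes tested, 200 changed), the limma step recovered 91% of genes with a log2 fold change of 1 and 54% of those at 0.5, with 2 unchanged genes called, and 0 of 20 unchanged lists were called. The changed genes were drawn from those at a mean of at least 5 FPKM. Far more genes, 4065, were called in the data, so the recovery there may differ. Simulated genes varied independently, so the 20 lists cannot show how often camera calls a list of correlated genes in error.

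Before the data were examined, 29 gene lists were fixed, covering lipid synthesis and use, glycolysis, hypoxia, replication and mitosis, Wnt, epithelial, mesenchymal and gut lineage genes, stress, p53, interferon, NF-kB and immediate early responses, markers of other cell types and RNA quality. The rule for named genes was fixed with them: HMGA1 and HMGA2, 12 lipid genes whatever their values, the 8 highest and the 8 lowest log2 fold changes among called genes with established symbols and groups that did not overlap (chance alone gives 10% for 3 against 3), and up to 4 called members of each list. The text gives values for part of 105 genes that it names, and some others are not reported here. Genes outside it are said to be named after their values were seen. Gene names were those of the table, with current symbols matched by ID. Of the Ensembl IDs, 30003 were found in GENCODE 29, which gave coordinates and transcripts, and 19610 in the same version. The ID of BOP1 in the table was not among them. In 41 of these 105 genes an exon overlaps another gene in GENCODE 29, mostly on the opposite strand, and reads of such pairs may not be separable. List members missing from the table were not analysed here.

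The alternatives chosen with them were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, quantile and median-of-ratios scaling, TPM (FPKM rescaled to the same total in each library), the replicate number as a block, no trend, robust eBayes and leaving out each library. An alternative without mitochondrially encoded genes was added after seeing the data. All per-sample columns were used.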

Results

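Poly-A RNA from HT29, an established human colorectal cancer cell line, was sequenced in 6 libraries. 3 libraries (shNC) came from cells with a control hairpin RNA, and 3 (shHMGA1) from cells in which HMGA1 was stably knocked down by a hairpin RNA against it. HMGA1 is a chromatin protein that binds AT-rich DNA. The series asks how it affects gene expression, and its stated interest is lipid synthesis. The table gave FPKM for 31164 genes, with library totals from 807156 to 838067. Read counts per library were not used here, so depth is known only in relative terms: low values put the 6 libraries at 0.69 to 1 times the depth of shNC replicate 1. Correlations of log2(FPKM + 1) were 0.980 to 0.988 within the groups and 0.973 to 0.977 between them, so each library was closer to its own group than to the other. The first principal component (42% of the variance) separated the groups. The second (18.3%) set shHMGA1 replicate 1, at -26.67, apart from shHMGA1 replicate 2, at 17. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

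HMGA1 itself was lower in the knockdown, at 513 ± 50.1 FPKM against 816 ± 35.1 in the controls (SD, n = 3 each), or 62.8% of the control level. The log2 fold change was -0.67 (SE 0.08, adjusted p = 0.0018), and each knockdown library lay below each control library. An exact permutation test of the 6 values gave p = 0.1 (two-sided), the smallest that 3 against 3 allows. HMGA1 (ENSG00000137309.19) lies on chromosome 6 from 34236873 to 34246231 in hg38. Its processed pseudogenes share its sequence, and HMGA1P8, for example, was listed at 2.47 FPKM in the controls (named after its value was seen), so HMGA1 reads could be split among them. HMGA2, the related chromatin protein, rose from 46.6 ± 1.63 to 67.9 ± 4.43 FPKM (log2 fold change 0.53, SE 0.06, adjusted p = 0.00188).

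The knockdown cells had more RNA for the efflux pumps ABCG2 and ABCC2 and less RNA for the secreted proteins CCN2 and IGFBP3. Most changes were small on this scale. Of 14304 genes tested, 2307 were higher and 1758 lower in shHMGA1 (adjusted p under 0.05), and of these 17 were at least 2-fold higher and 109 at least 2-fold lower. The 2-fold counts depend on the pseudocount, with 50 and 193 at 0.1 and 5 and 37 at 5. The balance was not the same in every setting: without mitochondrially encoded genes, an alternative chosen after seeing the data, 1853 were higher and 2055 lower. ABCG2, which exports drugs and urate, went from 1.39 ± 0.195 to 9.66 ± 2.48 FPKM (log2 fold change 2.13, SE 0.18, adjusted p = 0.000874). ABCC2, which exports conjugated compounds, went from 24.97 ± 1.01 to 61.1 ± 8.96 (log2 fold change 1.25). The RAS-like GTPase RERG (1.36), the receptor GPR15 (1.07), the gap junction protein GJA1 (1.05) and the host transcript MIR4527HG (1.72) also rose, as log2 fold changes. BOP1, a factor of ribosome assembly, rose unevenly. Its value was 14.3 FPKM in shHMGA1 replicate 1 and 46.9 and 45.5 in the other knockdown libraries, against 11.1 ± 2.34 in the controls (log2 fold change 1.44, adjusted p = 0.0427).

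Among the genes that fell, CCN2, a matrix-associated growth regulator, went from 11.9 ± 0.217 to 1.61 ± 0.58 FPKM (log2 fold change -2.34, SE 0.16, adjusted p = 0.000494). The IGF carrier IGFBP3 fell from 7.39 ± 0.399 to 0.96 ± 0.372 FPKM (log2 fold change -2.11). The homeobox genes HOXB8 (-2.06) and HOXB3 (-1.98), the calcium sensor VSNL1 (-2.06), the hypoxia-induced ANKRD37 (-2.05), the surface protein SUSD2 (-1.91) and the decoy receptor TNFRSF6B (-1.90) made up the rest of the 8 lowest log2 fold changes. Exons of HOXB3 overlap HOXB4 and HOXB6, and those of TNFRSF6B overlap an RTEL1 readthrough transcript, so their reads are not fully separable. Counts of called genes moved by over 1.5 times without shNC replicate 1 (1138 higher, 1001 lower), shNC replicate 2 (1279 and 952) or shHMGA1 replicate 3 (1173 and 1055). Without shHMGA1 replicate 3 MIR4527HG was not called (adjusted p = 0.0506), and BOP1 was called only without shHMGA1 replicate 1, with an adjusted p of up to 0.128 in the other leave-one-out fits.

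The genes of fatty acid synthesis did not move together. FASN, the fatty acid synthase, stood at 172 ± 1.88 FPKM in shNC and 163 ± 4.2 in shHMGA1 (log2 fold change -0.08, SE 0.04, adjusted p = 0.203), and ACLY, which makes cytosolic acetyl-CoA, at 107 ± 0.436 and 110 ± 7.02 (0.03, adjusted p = 0.739). ACACA, the acetyl-CoA carboxylase that commits acetyl-CoA to fatty acids, was higher by FPKM, at 50.3 ± 2.92 against 35.9 ± 0.357 (log2 fold change 0.47, SE 0.05, adjusted p = 0.00198). For the same gene the authors' deposited table gave a log2 fold change of -0.25 (adjusted p 4.04e-06), the opposite direction, so the direction of ACACA (chromosome 17) is open. The desaturase SCD was slightly lower, at 270 ± 2.48 against 295 ± 4.36 FPKM (log2 fold change -0.13, adjusted p = 0.0453). That call was lost when any 1 of the 6 libraries was left out, with adjusted p from 0.06 without shHMGA1 replicate 1 to 0.151 without shNC replicate 2.

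Of 25 members of the fatty acid synthesis list that were tested, 3 rose (MCAT, ME1, named after its value was seen, and, with its direction open, ACACA), 3 fell (SCD, SCD5 and ELOVL3) and 19 did not pass. With the authors' direction for ACACA, 2 rose and 4 fell. The counts by FPKM were 3 and 2 adjusted over the list alone, and the list as a whole did not pass (median log2 fold change 0.04, adjusted p = 0.936). MCAT, of mitochondrial fatty acid synthesis, rose from 14.6 ± 0.707 to 20.7 ± 2.3 FPKM, and the desaturase SCD5 fell from 24.9 ± 0.479 to 20.3 ± 1.52. None of the 3 that fell was called without shHMGA1 replicate 3, shNC replicate 2 or shNC replicate 3 (0 of 25 in each), and 1 was called without shHMGA1 replicate 2 or shNC replicate 1. All 3 stayed below 0 with any library left out (SCD -0.139 to -0.12, SCD5 -0.342 to -0.253, ELOVL3 -0.325 to -0.211).

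**Figure D1:**
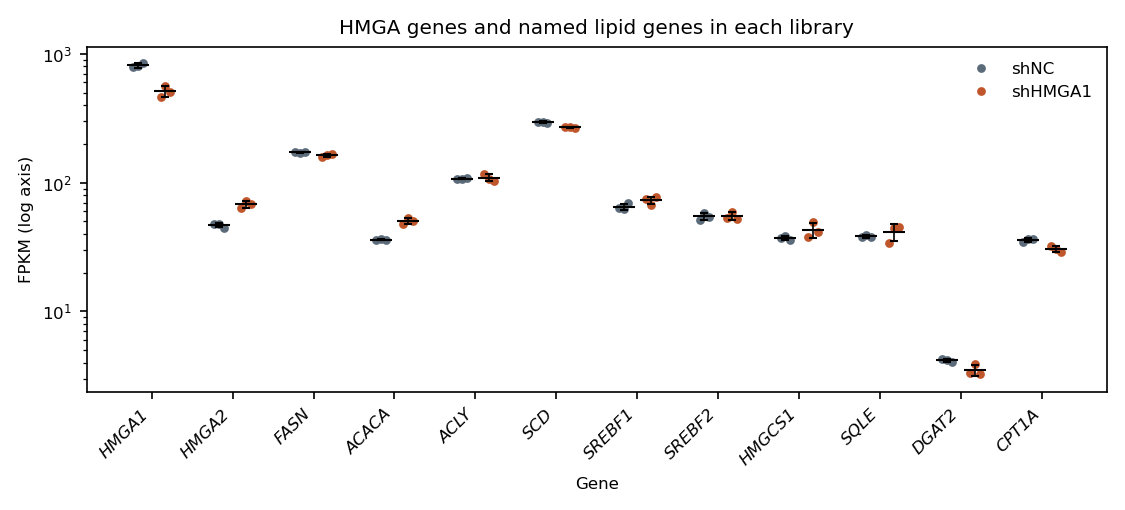
FPKM on a log axis for HMGA1, HMGA2 and 10 lipid genes named before the data were examined, with each of the 3 shNC and 3 shHMGA1 libraries as a point and the mean ± SD as a black bar. HMGA1 fell from 816 to 513 FPKM, while FASN stood at 172 and 163.

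In cholesterol synthesis, 7 of 20 tested enzymes rose and 0 fell (7 and 0 adjusted over the list alone). They included the sterol isomerase EBP, from 42.0 ± 2.79 to 57.9 ± 1.91 FPKM (log2 fold change 0.46, SE 0.06, adjusted p = 0.0031), and the mevalonate kinase MVK, from 12.2 ± 1.28 to 16.1 ± 0.796 (0.38). HMGCS1, a synthase early in the pathway, had a log2 fold change of 0.20 (SE 0.09, adjusted p = 0.147) and the squalene epoxidase SQLE one of 0.09 (adjusted p = 0.55), and neither passed. Both passed without shHMGA1 replicate 1 (0.28, adjusted p = 0.041, and 0.22, adjusted p = 0.017), and SQLE had 0.025 to 0.221 with any library left out. The list did not pass as a whole (median 0.10, adjusted p = 0.267). The count of 7 was 2 without shNC replicate 1, shNC replicate 2 or shHMGA1 replicate 3, and 4, with 2 that fell, without shHMGA1 replicate 2, and MVK was not called without shNC replicate 1 (adjusted p = 0.0513). Without mitochondrially encoded genes 6 rose and 2 fell.

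NPC2, a carrier of lysosomal cholesterol, fell from 217 ± 9.17 to 164 ± 6.39 FPKM (log2 fold change -0.40, SE 0.05, adjusted p = 0.00277), and INSIG2, which holds back SREBP processing, from 24.5 ± 0.527 to 14.0 ± 4.13 (-0.80). Of 17 members of the SREBP pathway and sterol uptake list, 4 fell and 0 rose (4 and 0 adjusted over the list alone). The transcription factors SREBF1 (log2 fold change 0.16, adjusted p = 0.124) and SREBF2 (0.01, adjusted p = 0.952) did not pass. The list was lower (median -0.13, adjusted p = 0.0287), but not with an estimated correlation (adjusted p = 0.351 with an estimated correlation). Without shNC replicate 1, shNC replicate 2, shNC replicate 3 or shHMGA1 replicate 3 the count was 2, and it was 7 without shHMGA1 replicate 1. INSIG2 was not called in 4 of the leave-one-out fits (adjusted p of up to 0.0608).

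Genes for storing and modifying lipids went both ways. In the triglyceride and lipid droplet list, 2 of 21 rose and 3 fell (5 and 5 adjusted over the list alone), with seipin (BSCL2) from 14.3 ± 1.12 to 21.9 ± 2.03 FPKM and the droplet coat protein PLIN3 from 151 ± 4.7 to 125 ± 5.96. DGAT2, which makes triglycerides, had a log2 fold change of -0.21 (SE 0.09, adjusted p = 0.115). In the phospholipid and sphingolipid list, 2 of 27 rose and 5 fell (2 and 5 adjusted over the list alone). PTDSS2, which makes phosphatidylserine, rose from 16.4 ± 1.64 to 23.4 ± 0.757 FPKM, and UGCG, which makes glucosylceramide, fell from 13.5 ± 0.306 to 10.3 ± 0.616. Neither list passed as a whole (adjusted p = 0.466 and 0.307). The 3 that fell in the first list were 1 without shNC replicate 1, 2 or 3 or without shHMGA1 replicate 2 or 3, and the 5 in the second were 1 without shNC replicate 1 or 2 or shHMGA1 replicate 3, 2 without shHMGA1 replicate 2 and 3 without shNC replicate 3. The 2 that rose in the first list were 1 without shNC replicate 1 or 3 or shHMGA1 replicate 3 and 5 without shHMGA1 replicate 1.

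For fatty acid use, 3 of 26 members of the oxidation list rose and 5 fell (3 and 6 adjusted over the list alone; median -0.10, adjusted p = 0.111). The nuclear receptor PPARA fell from 8.15 ± 1.46 to 3.86 ± 0.876 FPKM (log2 fold change -0.92, SE 0.16, adjusted p = 0.00813), and ACADM, of medium-chain oxidation, rose from 31.4 ± 0.452 to 41.9 ± 2.11 (0.40). CPT1A, which brings fatty acids into mitochondria, was lower (-0.22, adjusted p = 0.0294), a call kept only without shHMGA1 replicate 1 among the leave-one-out fits and otherwise at up to 0.0996. In the list for uptake, lipolysis and lipoproteins, 3 of 19 rose and 7 fell (4 and 7 adjusted over the list alone; adjusted p = 0.246 with camera, and 0.014 with fry). The sterol exporter ABCG1 fell from 3.16 ± 0.189 to 1.61 ± 0.243 FPKM, and ACSL4, which activates polyunsaturated fatty acids, from 28.3 ± 1.83 to 20.3 ± 1.84. The 5 of the oxidation list were 1 without shNC replicate 2 or 3, 2 without shHMGA1 replicate 3 and 3 without shNC replicate 1, and the 7 of the uptake list were 4 without shNC replicate 2. The 3 that rose were 1 without shNC replicate 1 in both lists, and in the oxidation list also without shNC replicate 2 or shHMGA1 replicate 2 or 3. In the oxidation list 8 fell without mitochondrially encoded genes.

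The hypoxia list was lower, and so were a pair of glucose transporters, while most glycolysis genes were not called. The transporters SLC2A1 and SLC2A3 fell from 263 ± 15.4 to 137 ± 12.6 FPKM (log2 fold change -0.94, SE 0.08, adjusted p = 0.000823) and from 11.97 ± 0.641 to 4.56 ± 0.96 (-1.24, SE 0.13, adjusted p = 0.00146). Of 24 glycolysis genes tested, 9 fell, 2 rose and 13 did not pass (14 fell and 4 rose adjusted over the list alone), with a median of -0.17 (adjusted p = 0.00298, and adjusted p = 0.562 with an estimated correlation). Of 19 genes of the hypoxia response, 12 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.50 (adjusted p = 9.59e-07, and adjusted p = 0.51 with an estimated correlation). ANKRD37 fell from 16.5 ± 0.863 to 3.22 ± 0.348 FPKM, NDRG1, a stress-induced protein, from 158 ± 5.06 to 77.1 ± 5.61, and the secreted lipase inhibitor ANGPTL4 from 17.5 ± 0.896 to 6.38 ± 1.25. CA9, a carbonic anhydrase of the same response, was the member that rose (log2 fold change 0.80; named after its value was seen). The 9 glycolysis genes that fell were 4 without shHMGA1 replicate 3, and the 2 that rose were 0 without that library or shNC replicate 1 and 1 without any other. Without mitochondrially encoded genes 0 rose.

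Genes of DNA replication rose. The helicase subunits MCM5 and MCM2 went from 45.7 ± 1.74 to 75.7 ± 3.04 FPKM (log2 fold change 0.72, SE 0.05, adjusted p = 0.000556) and from 61.7 ± 3.38 to 94.5 ± 5.85 (0.61). The replication factor CDC45 went from 17.4 ± 1.39 to 29.4 ± 4.44, and E2F2, a transcription factor of S phase entry, from 5.75 ± 0.427 to 10.4 ± 0.108 (0.76). Of 40 members of the DNA replication and G1/S list, 35 rose and 2 fell, also when adjusted over the list alone. The 2 that fell were the G1 cyclin CCND1 (log2 fold change -0.25) and its kinase partner CDK6 (-0.47), named after their values were seen. They were 0 without shNC replicate 1 or 2 and 1 without shNC replicate 3 or shHMGA1 replicate 3. The list median was 0.45 (adjusted p = 5.38e-13, and adjusted p = 0.351 with an estimated correlation).

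Of 31 mitosis genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.00298, and adjusted p = 0.585 with an estimated correlation). The spindle factor TPX2 rose from 115 ± 1.74 to 152 ± 13.5 FPKM (log2 fold change 0.39, SE 0.07, adjusted p = 0.00715) and the spindle motor KIF11 from 18.9 ± 1.25 to 26.8 ± 3.3 (0.47, SE 0.10, adjusted p = 0.0125). The count of 12 was 3 without shNC replicate 1, 4 without shNC replicate 2 or shHMGA1 replicate 3, 7 without shNC replicate 3, 8 without shHMGA1 replicate 1 and 18 without shHMGA1 replicate 2, and it was 7 without mitochondrially encoded genes. In the count for DNA replication, between 29 and 34 of 40 rose with any library left out.

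The Wnt and mesenchymal lists were lower, with about as many members called as not. AXIN2 and RNF43, feedback inhibitors of Wnt signalling, went from 15.1 ± 0.281 to 7.15 ± 0.989 FPKM (log2 fold change -0.99, SE 0.09, adjusted p = 0.00121) and from 46.8 ± 2.63 to 22.9 ± 1.12 (-0.999, SE 0.06, adjusted p = 0.000316). NOTUM (-0.62) and SP5 (-0.76) fell with them. Of 17 Wnt and intestinal stem cell genes tested, 9 fell, 0 rose and 8 did not pass (10 fell and 0 rose adjusted over the list alone), with a median of -0.42 (adjusted p = 2.63e-05, and adjusted p = 0.176 with an estimated correlation). Of 12 mesenchymal genes, 7 fell, 0 rose and 5 did not pass (9 fell and 0 rose adjusted over the list alone), with a median of -0.58 (adjusted p = 2e-05, and adjusted p = 0.176 with an estimated correlation). Fibronectin (FN1) fell from 13.0 ± 0.482 to 4.63 ± 0.743 FPKM and vimentin (VIM) from 5.81 ± 0.144 to 2.31 ± 0.746. Between 6 and 10 Wnt genes and between 6 and 8 mesenchymal genes fell with any library left out, and 1 mesenchymal gene rose without shHMGA1 replicate 2.

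Epithelial genes went both ways: 2 of 21 rose and 6 fell (2 and 6 adjusted over the list alone; median -0.06, adjusted p = 0.267 with camera, and 0.0471 with fry). The transcription factor GRHL2 rose from 7.16 ± 0.439 to 11.2 ± 1.76 FPKM, and the desmosomal protein DSP fell from 64.7 ± 2.96 to 48.5 ± 2.44. Few genes of the differentiated gut lineages reached the level at which genes were tested. HNF4A fell (log2 fold change -0.58, adjusted p = 0.0159) as the 1 called gene of 5 in the enterocyte list (1 adjusted over the list alone; adjusted p = 0.389). FOXA3 rose (0.30, adjusted p = 0.0363) as the 1 of 3 in the goblet list (1 adjusted over the list alone; adjusted p = 0.662). In the enteroendocrine list 0 of 3 passed by limma, 0 adjusted over the list alone, with adjusted p = 0.914 for the list, whose median was 0.04 while the set test pointed down. The 6 epithelial genes that fell were 3 without shNC replicate 2, shNC replicate 3 or shHMGA1 replicate 3. HNF4A was not called in 4 leave-one-out fits (adjusted p of up to 0.0561) and FOXA3 in 5 (up to 0.119).

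The interferon response list was lower, with most members not called: 8 of 24 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00947, and adjusted p = 0.51 with an estimated correlation). IFI6 fell from 63.3 ± 1.88 to 28.4 ± 3.12 FPKM (log2 fold change -1.14, SE 0.08, adjusted p = 0.000485) and the interferon regulator IRF7 from 11.3 ± 0.459 to 7.15 ± 0.56. Of 13 NF-kB and inflammation genes, 2 rose and 3 fell (3 and 5 adjusted over the list alone; median 0, mean -0.12, adjusted p = 0.389), with the chemokine CXCL8 down from 4.45 ± 0.0985 to 1.37 ± 0.415 FPKM. Of 20 p53 targets, 4 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.532), among them the pro-apoptotic BAX, from 108 ± 10.4 to 78.0 ± 5.49 FPKM. Of 23 genes of the integrated stress and unfolded protein responses, 4 rose and 5 fell (4 and 6 adjusted over the list alone; adjusted p = 0.408). The amino acid transporter SLC7A5 rose from 99.98 ± 2.26 to 139 ± 3.12 FPKM and the endoplasmic reticulum chaperone DNAJB9 fell from 8.28 ± 0.272 to 5.68 ± 0.471. The 8 interferon genes that fell were 5 without shNC replicate 1, shNC replicate 2 or shHMGA1 replicate 3, and the 2 that rose were 0 without shNC replicate 2 and 1 without shNC replicate 1 or shHMGA1 replicate 3. The 5 stress response genes that fell were 8 without shHMGA1 replicate 1. The 4 p53 targets that rose were 1 without shNC replicate 1, shNC replicate 3 or shHMGA1 replicate 3 and 0 without shNC replicate 2, while 7 fell without shHMGA1 replicate 1. The 2 NF-kB genes that rose were 1 without shHMGA1 replicate 1 and 0 without any other library, and 5 fell without shHMGA1 replicate 2. Without mitochondrially encoded genes 1 rose and 5 fell.

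Immediate early genes, which respond within minutes to growth signals and to handling of cells, were lower in the knockdown and uneven within it. All 21 tested had log2 fold changes below 0 (median -0.84), of which 7 passed and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 3.16e-06, and adjusted p = 0.562 with an estimated correlation). EGR2 fell from 6.87 ± 0.207 to 1.93 ± 1.06 FPKM (log2 fold change -1.50, SE 0.26, adjusted p = 0.00744) and KLF6 from 54.5 ± 2.77 to 27.8 ± 9.97. EGR1 shows the unevenness, with 222 FPKM in shHMGA1 replicate 1, 44.96 in replicate 2 and 117 in replicate 3, against 231 ± 4.64 in the controls (named after its values were seen). Without shHMGA1 replicate 1, which the second principal component also set apart, 17 fell and the median was -1.26, and without shHMGA1 replicate 2 the median was -0.52. KLF6 was not called in 3 leave-one-out fits, with adjusted p of up to 0.0608.

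**Figure D2:**
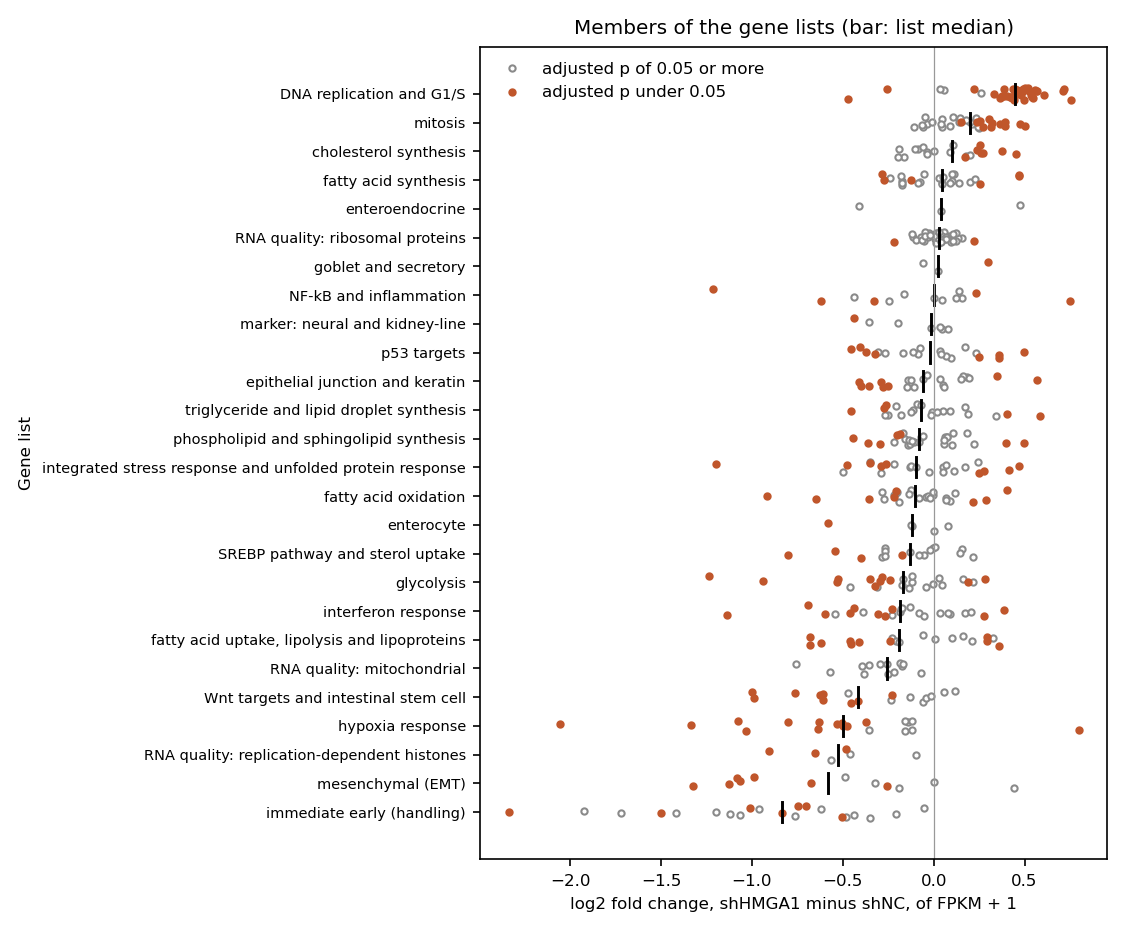
Log2 fold change (shHMGA1 minus shNC, on log2 of FPKM + 1) of each tested member of the 26 lists with at least 3 tested members, filled where the adjusted p was under 0.05, with the list median as a bar. DNA replication has the highest median, 0.45, and immediate early genes the lowest, -0.84. Without shHMGA1 replicate 2 the lowest median was that of the mesenchymal genes (-0.53, against -0.52 for immediate early genes).

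Among measures of RNA quality, mitochondrially encoded and histone transcripts were lower as sets. Mitochondrially encoded genes took 12.3 ± 1.1% of FPKM in shNC and 9.97 ± 2.18% in shHMGA1 (exact permutation p = 0.3, two-sided), with 12.5% in shHMGA1 replicate 1 and 8.94% and 8.5% in replicates 2 and 3. All 13 were below 0 (median -0.26) with 0 past the threshold by limma, 0 adjusted over the list alone, and 11 without shHMGA1 replicate 1. As a set they passed (adjusted p = 0.0116), but not with an estimated correlation (adjusted p = 0.585 with an estimated correlation), nor without shHMGA1 replicate 2 (0.0635) or replicate 3 (0.102). Of 6 replication-dependent histone genes, a class whose transcripts usually lack a poly-A tail, 3 fell (5 adjusted over the list alone). The list median was -0.52 (adjusted p = 0.0116, and adjusted p = 0.412 with an estimated correlation). HIST1H2BD, for example, fell from 6.81 ± 1.67 to 3.12 ± 0.162 FPKM. The libraries were selected with poly-T beads, and whether the histone RNA measured had such a tail was not tested. Of 40 ribosomal protein genes, RPS12 rose and RPL37 fell (0 and 0 adjusted over the list alone; median 0.03, adjusted p = 0.625), and each lost its call in 5 leave-one-out fits (adjusted p of up to 0.125).

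Markers of other cell types were mostly under the level at which genes were tested. The endothelial list had 0 of 8 genes at a mean of 1 FPKM, and the highest was 0.14. The blood and immune list had 2 tested and 0 called by limma (highest mean 1.65 FPKM, CD68), and the fibroblast list 1 tested and 0 called (COL1A1, 10.0 FPKM). In the list for neural and kidney lines, 7 were tested and MAP2 fell (1 adjusted over the list alone; log2 fold change -0.44, adjusted p = 0.00727 for the gene, and 0.389 with camera and 0.0385 with fry for the list), while TUBB3 was at a mean of 172 FPKM over the 6 libraries. CD68, COL1A1 and TUBB3 were named after their values were seen.

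The authors' deposited table holds its own test of the same groups. It had 5647 genes with an adjusted p under 0.05, 2887 higher and 2760 lower, and marked 81 as up and 372 as down. Of the 4065 genes called here, 3662 were also past 0.05 in the authors' deposited table, 382 were not and 21 had no adjusted p there, while 1692 genes tested here passed in that table alone. ACACA and TMEM164 were past 0.05 in both with opposite signs (TMEM164 named after its values were seen). For HMGA1 the authors' deposited table gave a log2 fold change of -0.68, and SREBF1 passed there (0.18, adjusted p 0.0054) and not here.

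**Figure D3:**
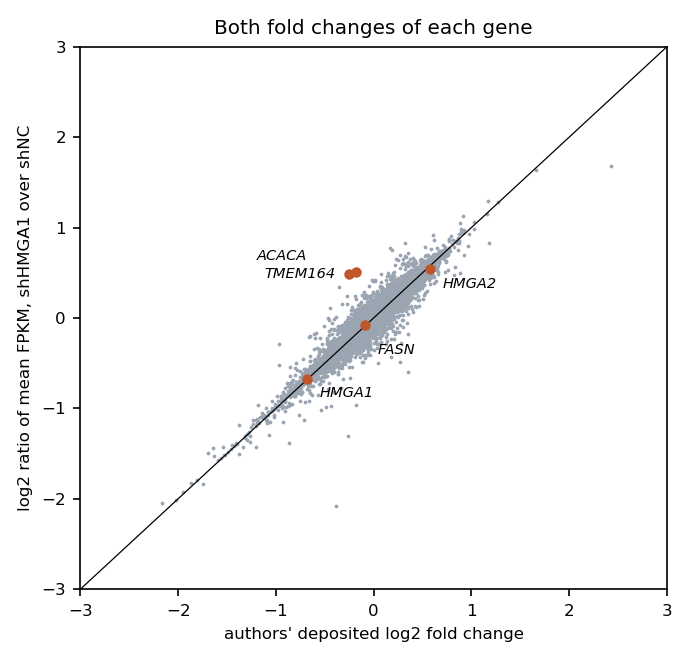
Log2 ratio of mean FPKM (shHMGA1 over shNC, y axis) against the log2 fold change of the authors' deposited table (x axis) for 10923 genes with a level of at least 200 in both groups of that table, with the line of equality. HMGA1, HMGA2 and FASN lie near the line, and ACACA lies above it, with 0.48 on the y axis and -0.25 on the x axis.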

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

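The alternative without mitochondrially encoded genes was chosen after seeing the data, and all others before. HMGA1 kept its direction and its call under each alternative run. A count test on reads was planned only for a table with counts and was not run. Of 98 called named genes, 33 lost the call in at least 1 leave-one-out fit and 24 without a filter, and at most 8 under any other setting. The numbers 1 to 3 did not pair the libraries (correlations of deviations 0.02, -0.036 and 0.041). With the replicate block 1913 genes were higher and 1495 lower.

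The count of higher genes was 1478 without a filter, where more genes were tested. With one library left out it ran from 1138 to 2626, and that of lower genes from 952 to 1973. Without mitochondrially encoded genes they were 1853 and 2055, the only setting with more lower than higher. Genes at least 2-fold higher or lower numbered 50 and 193 with pseudocount 0.1 and 5 and 37 with pseudocount 5, as the pseudocount shrinks low genes. Those 2-fold higher numbered 7 at a mean of at least 5 FPKM, and 17 to 27 with one library left out.

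With camera at an estimated correlation, adjusted p was 0.351 for the SREBP pathway and for DNA replication, 0.562 for glycolysis and immediate early genes, 0.51 for hypoxia and interferon, 0.585 for mitosis and mitochondrial genes, 0.176 for Wnt and mesenchymal genes and 0.412 for histones, so none of the calls of the fixed lists held. The estimate was -0.051 for Wnt and -0.009 for the SREBP pathway, below the preset 0.01. Correlation between members therefore does not account for the loss in those lists. What does was not tested, and it may also add to the loss in the other lists. The estimate reached 0.759 for immediate early and 0.886 for mitochondrial genes. With fry, mitosis (0.135), immediate early (0.0642) and mitochondrial genes (0.247) did not pass, while 3 of the fixed lists passed that camera did not call, all lower: fatty acid uptake (0.014), epithelial (0.0471) and neural and kidney line markers (0.0385). Fatty acid oxidation passed, lower, with quantile scaling (0.0366) and without shHMGA1 replicate 2 (0.0362). The mitochondrial list gave 0.329 with quantile scaling and 3.75e-06 to 0.102 with one library left out.

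Directions turned only where no test was passed. Fatty acid synthesis pointed down at a mean of at least 5 FPKM (adjusted p = 0.935), with quantile scaling (0.578), with the replicate block (0.951), without mitochondrially encoded genes (0.98) and without shNC replicate 1 or shHMGA1 replicate 2 (0.783 to 0.971 over all 6 leave-one-out fits, of which the other 4 pointed up). The goblet list turned without a filter (0.667), the enteroendocrine list with quantile scaling (0.954), fry (0.995), without mitochondrially encoded genes (0.995) and without shHMGA1 replicate 1 (0.783 to 0.96 over all 6), and ribosomal proteins without mitochondrially encoded genes (0.98) and without shNC replicate 1 or shHMGA1 replicate 2 (0.103 to 0.96 over all 6). ACLY had log2 fold changes of -0.01 with quantile scaling and without mitochondrially encoded genes (-0.023 to 0.065 over all 6, below 0 without shHMGA1 replicate 1). SREBF2 had -0.047, -0.006 and -0.03 with quantile scaling, median-of-ratios scaling and without mitochondrially encoded genes (-0.051 to 0.052 over all 6, below 0 without shNC replicate 1 or shHMGA1 replicate 2). Except where a reason is given, the cause was not tested. Scaling moved the median of all genes by under 0.1. Depth limits calls at low FPKM, where a read is a large step.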

Other observations

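The lists in the first paragraph were written after the values were seen, and among the tests of the 3 patterns those on library scaling, on mitochondrial RNA, on growth state, on single libraries, on HOXB genes without an overlap, on a shorter chromosome segment and on other splits of the libraries were chosen after the result was seen. Genes known to be induced by ERK signalling were lower in the knockdown: 13 of 20 fell and 0 rose (16 and 0 adjusted over the list alone; median log2 fold change -0.36, adjusted p = 5.16e-10 over these 5 lists, and adjusted p = 0.0166 with an estimated correlation). The EGFR ligand AREG fell from 227 ± 5.66 to 112 ± 0.586 FPKM (SD, n = 3 each), the receptor EPHA2 from 59.3 ± 1.44 to 25.9 ± 1.89 and the ERK phosphatase DUSP4 from 46.0 ± 0.681 to 21.8 ± 1.62. Of 20 YAP/TAZ targets 11 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 1e-06, and adjusted p = 0.0819 with an estimated correlation), with CRIM1 from 10.9 ± 0.651 to 5.59 ± 0.271 FPKM and FJX1, the member that rose, from 5.16 ± 0.207 to 8.67 ± 0.77. Drug efflux pumps went both ways: with ABCG2 and ABCC2 up, ABCB1 fell from 2.16 ± 0.157 to 0.953 ± 0.0611 FPKM, and the list of 7 had 2 up and 1 down (3 and 1 adjusted over the list alone; adjusted p = 0.392 with camera, and 0.00586, higher, with fry). The lists were chosen on these libraries and are not independent evidence of their direction. They also share genes with the fixed lists. EGR1 (ERK) and CCN2 (YAP/TAZ) are in the uneven immediate early list, and CCND1 (ERK) is in the DNA replication list. Their p-values were adjusted over 5 lists and not over 26, so they cannot be ranked against those of the fixed lists.

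ACACA, with a FPKM ratio of 0.48 and an authors' fold change of -0.25 (log2), was the 7th widest gap among 10923 genes compared, of which 124 differed by over 0.3. The median gap over all of them was 0.014, which argues against a scaling difference between the measures, and ACACA stayed at 0.43 or more in each of the 6 leave-one-out fits, which argues against a single aberrant library. A changed mix of transcripts of different length, which FPKM and counts weigh differently, remains a candidate explanation: 119 genes with a wide gap had a median of 2 more annotated transcripts than genes matched on level (9 against 7, permutation p = 0.041, one-sided, 10000 draws). Whether HMGA1 acts on the choice of ACACA transcripts was not tested, and read-level data were not used here.

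DNA replication genes were higher, with a list median of 0.45 (camera adjusted p = 5.38e-13, and 0.351 with an estimated correlation). The median was 0.405 to 0.462 over 3 scaling alternatives, 0.414 without mitochondrially encoded genes, and 0.488 (95% bootstrap interval 0.428 to 0.518) after the trend of log2 fold change on GC content and transcript length was removed, which argues against each of these as the whole cause. The interval comes from resampling genes of the list and not libraries, so it leaves out the spread between replicates. Growth state at harvest stays open and cannot be told apart from the knockdown, because no label gives the density or harvest of the cultures. Hypoxia genes had a median of -0.501 (camera adjusted p = 0.51 with an estimated correlation), as denser control cultures may also give. An effect of the knockdown itself stays open, untested.

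HOXB genes were lower as a group, by a list written after the values were seen: 7 of 9 fell and 0 rose (7 adjusted over the list alone; median -0.96, adjusted p = 2.89e-07, and adjusted p = 0.0355 with an estimated correlation). The p-values were adjusted over the 5 lists written after the values were seen. The HOXB list was chosen on these libraries and is not independent evidence of its direction. Of 9 HOXA genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.206 with camera, and 0.00586, lower, with fry). 27 other coding genes within 1 Mb of the cluster on chromosome 17 had a median of 0.091. The 95% bootstrap interval, from resampling these genes and not libraries, was 0.002 to 0.157. These values argue against loss of a segment that spans 1 Mb on each side. The nearest tested coding gene on one side, SKAP1, fell (log2 fold change -1.026, adjusted p = 0.00118), and on the other TTLL6 did not pass (-0.335, adjusted p = 0.171), both named after their values were seen. HOXB7 is annotated from 48607227 to 48633572, a span that holds HOXB8 and HOXB9, and its lower end lies between HOXB6 and HOXB8. Its log2 fold change was -0.071 (SE 0.054), which argues against loss of 1 shorter segment that covers the genes that fell. Separate smaller losses were not tested. Of the 7 that fell, HOXB3, HOXB4 and HOXB6 had an exon overlapping another of these HOXB genes. HOXB2 and HOXB5 overlapped only an antisense transcript, HOXB-AS1 and HOXB-AS3. Reads shared between neighbours may account for part of the fall of these 5. The remaining 2 had no exon overlapping any other gene of the cluster. Those 2, HOXB8 and HOXB9, fell by 0.995 or more, which argues against shared reads for them. An off-target effect of the hairpin RNA was not tested, and an effect of the HMGA1 knockdown stays open as a hypothesis.

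Other splits of the 6 libraries into 3 and 3 bear on both counts of called genes. The real split called 4065 genes and 126 at least 2-fold, and the highest of the others called 3 and 3. It was the only 1 of the 10 splits to call as many, and 10 splits are too few for a share under 0.05.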
